A study of Mus musculus with 15 samples.

How the data were processed

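Chromatin accessibility was measured by Omni-ATAC-seq, an ATAC-seq protocol in which a transposase inserts sequencing adapters into open chromatin, in mouse embryonic fibroblasts (MEFs) of a C57 background. Per the labels, the cells of 12 libraries carried a CRISPR activation construct (a guide-directed, cutting-deficient Cas9 fused to the VPR activator) with an mCherry reporter, had received guides against the Fosl2 gene, which encodes Fra2, or scrambled control guides, and had been sorted for mCherry and the surface protein THY1. The other 3 libraries came from MEFs treated for 3 days with 4 µM GSK343, an inhibitor of the histone methyltransferase Ezh2, followed by a washout day. The labels of the samples and of the series differ on the days after infection: 3 and 10 in most sample labels, 4 and 11 in the series design, and the groups are therefore called early and late. Early control 3 and the Ezh2 inhibitor libraries carry day 4 in their sample labels. Each of the 5 groups holds 3 libraries, taken from the sample titles. The labels do not say whether the inhibitor cells were transduced or sorted, and their titles carry sheet numbers 27 to 29 against 1 to 12 for the other libraries. Nothing states that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

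The values start from a deposited table of raw read counts per consensus peak, with 15 libraries and 206367 peaks, of which 206366 are 502 bp wide. The count columns hold whole numbers that sum to between 6.75 and 25.3 M (mega) reads per library, and 0 columns were left unused. A deposited list of the same peaks carries a score of undescribed origin and was used only to check positions, which matched for all 206367 peaks. The 15 deposited peak lists, 1 per library, give for each peak a fold enrichment (a ratio over the caller's background) and −log10 values of p and q. Peaks were called with MACS2 and coordinates are in mm10, per the submitters' processing notes, with no version given. The peak names in the deposited lists hold the words trim, bowtie, dedup and BAM. The aligner version, the read-shift setting, the counting tool and the method that made the consensus peaks are not given in the sources used here. The smallest −log10 p in the deposited lists lay between 2.04 and 2.42, so the lists were called at a permissive threshold. PCR duplicates and reads that map to repeated sequence affect ATAC-seq counts, and how either was treated is not stated beyond the word dedup.

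Peaks were assigned to the nearest protein-coding gene interval of the RefSeq annotation of GRCm38.p6 (the assembly also named mm10), up to 100 kb from the peak centre. The annotation table used here holds 21631 protein-coding genes with their start and end but no strand, so transcription start sites could not be placed. In place of the planned promoter class, a peak was called a gene-end peak where its centre lay within 1 kb of either annotated end of a gene. By this rule 26743 peaks lay at gene ends, 97968 in gene bodies and 81656 outside genes, and 182983 (88.67%) received a gene. When all peaks were moved by 50 kb, 9972 fell within 1 kb of a gene end. A peak's nearest gene need not be the gene it regulates. No genome sequence was used here, so the planned motif test and the correction for GC content were not run. Coordinates are 1-based.

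Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, with TMM scaling, the default expression filter, which removed 18 peaks and left 206349, and 1 fit of all 15 libraries with a mean per group. Adjusted p-values are Benjamini-Hochberg values over all tested peaks of a comparison, and a peak was called at an adjusted p under 0.05 without a fold threshold. Levels are CPM (counts per mega reads in peaks, from cpm of edgeR) after TMM scaling, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. The 3-count floor lay between 0.119 and 0.444 CPM per library, which covers counting error only. The design gave 6 comparisons: early Fra2 against early control, late Fra2 against late control, Ezh2 inhibitor against early control, the difference of the Fra2 effects between times, late against early control, and early Fra2 against Ezh2 inhibitor.

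Before the data were examined, the tests, the alternatives, 19 gene lists and a rule for named genes were fixed. The lists cover AP-1 family genes, AP-1 target and wound genes, fibroblast identity, myofibroblast and contractile, YAP-TEAD target, Hox cluster, Polycomb-bound developmental regulator, PRC2 and PRC1 subunit, senescence and p53, pluripotency, adipogenic, chondrogenic and osteogenic, endothelial, epithelial, macrophage and immune, neuronal, skeletal and cardiac muscle, and interferon response genes, with ribosomal protein genes as a reference list. Of their 504 genes 500 were matched. Each list's peaks were compared with all other peaks by camera (limma 3.58.1), on log2 CPM from voom with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 57 tests of 19 lists and 3 comparisons. The rule names, per treatment comparison, the 8 genes of largest increase and the 8 of largest decrease among called peaks with a fitted mean of at least 1 CPM, no overlap between treated and control libraries and a gene within 100 kb. It adds peaks at Fosl2 and Ezh2 and, from each list, up to 4 genes with the smallest adjusted p, up to 2 higher and 2 lower. Some of the genes it names are not reported here. Every peak printed from this rule had its 3 treated libraries beyond all 3 controls, except Atf3, Hoxc13 and Sox17, and except peaks at Fosl2 and Ezh2; a separation of 3 from 3 arises by chance in 10% of peaks.

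Called peaks were compared between gene ends and other positions with Fisher's exact test, and counts of merged peak regions per library with two-sided exact permutation tests. Overlaps were made with bedtools 2.31.1. For effects that share control libraries, 3 sets of unchanged groups were simulated against those controls. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The alternatives were DESeq2 1.42.0, its median-ratio size factors in edgeR, total counts, TMM factors from gene-end peaks, cyclic loess offsets, other count filters, a replicate block, a fold threshold, only the groups compared, and leaving out each library in turn. Quality weights per library, thinning to the depth of the shallowest library and fits without early control 3 were added after the data were seen. On simulated counts built from the early Fra2 comparison with 20000 peaks, including 67 changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold, edgeR recovered 17.9%, 70.1% and 98.5% of them, and 5 of its 129 calls were false.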

Results

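Accessibility was measured at 206367 consensus peaks in 15 libraries of mouse embryonic fibroblasts (MEFs), primary connective tissue cells grown from embryos. The 5 groups of 3 libraries were early and late cells with scrambled guides, early and late cells with guides that direct a transcriptional activator to Fosl2, the gene of the AP-1 subunit Fra2, and cells treated with 4 µM of an Ezh2 inhibitor. Reads in peaks (M, mega) came to 19.4, 14 and 6.75 M in early controls 1 to 3 and 21.6, 12.7 and 13.6 M in the early Fra2 libraries. Late controls held 13.3, 17.3 and 17 M, late Fra2 libraries 23.4, 18.4 and 16.1 M, and Ezh2 inhibitor libraries 22.4, 21.6 and 25.3 M. On the first principal component (27.6% of variance) the 6 Fra2 libraries lay at 79.1 to 128, late controls at −36.9 to −18.6, inhibitor libraries at −74.9 to −60.6 and early controls at −122 to −105. Early control 3, the shallowest library, stood apart on the second component at −221.3, and its lowest correlation with a library of its group was 0.783, against at least 0.896 within the other groups.

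The first question was whether chromatin changed at the targeted gene itself. Peaks at Fosl2 (chromosome 5, 32136472 to 32157840, mm10) rose in both Fra2 comparisons, mostly past the annotated end of higher coordinate. Of 32 peaks within 10 kb of the gene, 9 rose with early Fra2 guides, 6 of them among the 8 peaks past that end. With late Fra2 guides 8 rose, 7 of them past that end, and 1 fell. The largest early rise lay 4.3 kb past the gene (32161859 to 32162360), at 6.54 ± 1.58 CPM against 2.01 ± 0.84 in controls (SD, n = 3), a log2 fold change of 1.81 ± 0.26 (SE; edgeR adjusted p = 8.25e-07). The same peak rose by 1.11 ± 0.27 in late cells (edgeR adjusted p = 0.00477). A peak 0.6 kb past the same end (32158186 to 32158687) rose by 1.08 ± 0.18 in early and 1.13 ± 0.17 in late cells. The most accessible peak of the locus, at the opposite end (32135561 to 32136062), stood at 42.9 ± 4.93 CPM against 43.8 ± 8.1 in early cells and at 38.1 ± 1.46 against 48.5 ± 5.65 in late cells. Neither difference passed the test (edgeR adjusted p = 0.888 and 0.13), although DESeq2 called the late one lower (−0.35), as did edgeR without early control 3 (−0.35), and cyclic loess put it at 0.09. With the Ezh2 inhibitor edgeR and DESeq2 each called 0 of the 32 peaks, 6 had an unadjusted edgeR p under 0.05, and without early control 3 edgeR called 4.

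**Figure D1:**
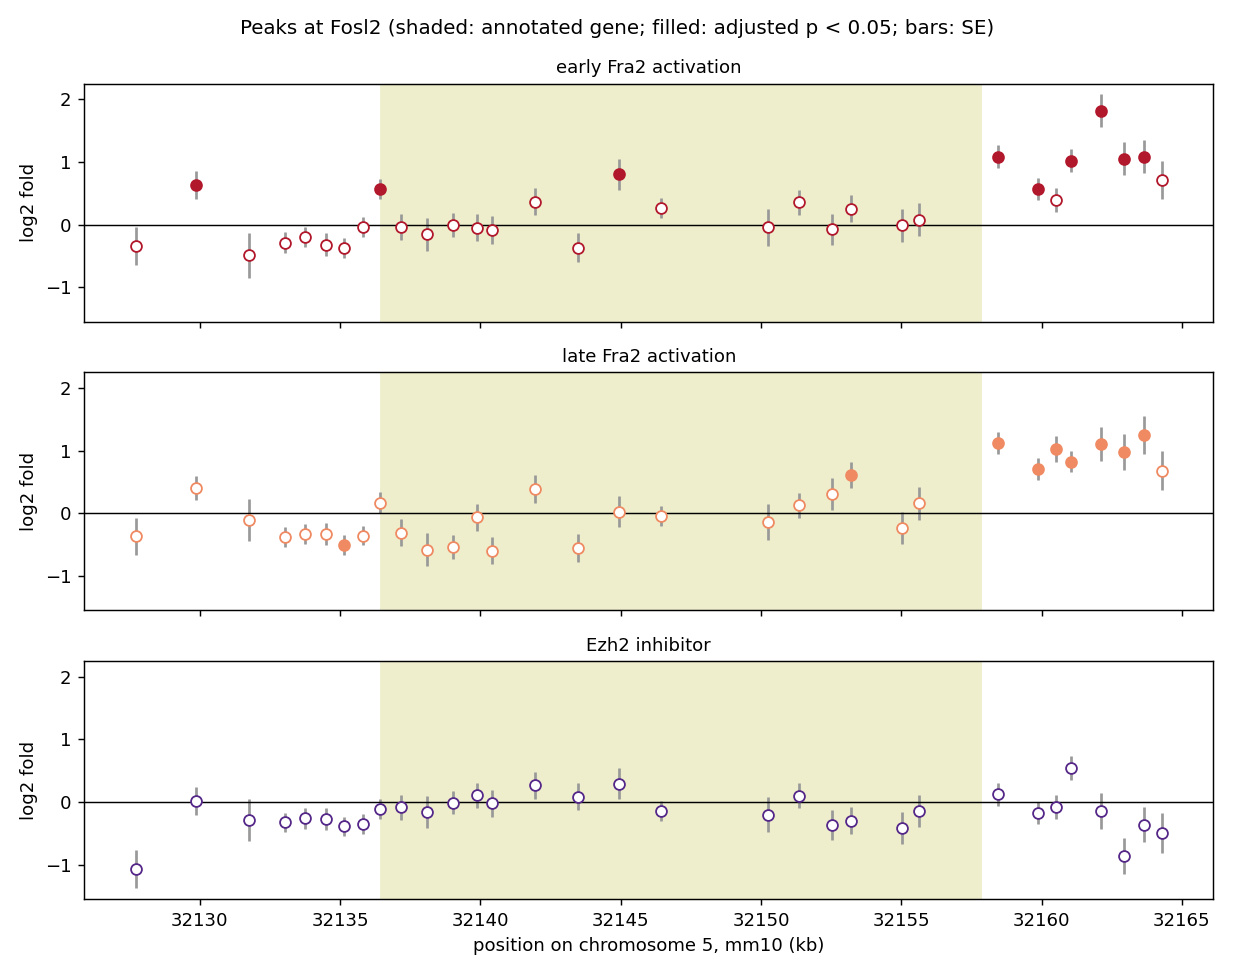
Fitted log2 fold changes (y axis, error bars SE) of the peaks within 10 kb of Fosl2 against position on chromosome 5 (x axis), for early Fra2, late Fra2 and Ezh2 inhibitor, with the annotated gene shaded and called peaks filled. Peaks past the gene end of higher coordinate rose in both Fra2 comparisons, up to 1.81, while the peak at the opposite end with the highest level did not pass the test.

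Early Fra2 activation gave 20791 peaks called higher and 10144 called lower, a split that depended on the scaling as described below. Plau, which encodes urokinase, gained at a peak 17.6 kb from the gene (chromosome 14, 20818817 to 20819318), from 2.72 ± 0.0925 to 6.47 ± 0.687 CPM (n = 3; log2 fold change 1.25 ± 0.20, SE; edgeR adjusted p = 4.43e-06). Plaur, its receptor, rose by 1.04 ± 0.17 at a gene-end peak. Fbn1, which encodes the microfibril protein fibrillin, rose from 7.34 ± 1.7 to 23.7 ± 2.3 CPM at a peak in the gene body (chromosome 2, 125306896 to 125307397; 1.65 ± 0.17; edgeR adjusted p = 9.23e-11). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 1.97 ± 0.19 at a peak 19.5 kb away. In the opposite direction, Fos, an AP-1 subunit itself, lost at a peak 1.8 kb from the gene (chromosome 12, 85478828 to 85479329), from 8.56 ± 1.46 to 3.47 ± 0.366 CPM (−1.31 ± 0.19; edgeR adjusted p = 5.98e-07). Cdkn1a, which encodes a cell-cycle inhibitor, fell from 8.2 ± 0.208 to 3.59 ± 0.963 CPM at a gene-end peak (chromosome 17, 29100543 to 29101044; −1.14 ± 0.18; edgeR adjusted p = 6.39e-06).

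Among the genes with the largest early gains were Asb9 (log2 fold change 3.48 ± 0.53), Map3k7, a kinase of TGF-beta and cytokine signalling (3.20 ± 0.44), and Ptprg, a receptor phosphatase (2.85 ± 0.44). Next came Rai14 (2.77 ± 0.48), Rsrc1 (2.75 ± 0.56), Sobp (2.65 ± 0.35) and F13a1, which encodes the catalytic chain of a clotting factor (2.64 ± 0.35). Their control levels were low: Asb9 rose in the gene body (chromosome X, 164499852 to 164500353) from 0.175 ± 0.182 to 2.27 ± 0.576 CPM, and F13a1 from 0.748 ± 0.0934 to 4.59 ± 0.435 CPM. At the same peaks of Asb9, Rai14 and Rsrc1 late scrambled controls also lay above early ones (log2 fold change 2.595, 2.348 and 2.115). The late Fra2 effect at the Rai14 peak was −0.12 ± 0.37. The largest losses were at Pam (−2.82 ± 0.48), Rnf169 (−2.71 ± 0.52), Fam180a (−2.58 ± 0.54), Lyzl1 (−2.56 ± 0.50), Apaf1, the scaffold of the apoptosome (−2.46 ± 0.41), Olfm3 (−2.40 ± 0.58), Myo18a (−2.34 ± 0.51) and Jakmip3 (−2.23 ± 0.53). In all 8 of these early control 3 had the highest level of the 3 controls, and all 8 were still called without that library, with smaller log2 fold changes: −1.45 for Myo18a, −1.68 for Jakmip3, −1.92 for Lyzl1 and −2.08 to −2.49 for the other 5.

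Among the lists, AP-1 target and wound genes had 81 of 669 peaks higher and 21 lower (81 and 21 adjusted over the list alone). Their mean lay 0.08 above that of all other peaks, which did not pass (camera adjusted p = 0.315). The 57 gene-end peaks of the list lay 0.26 above other gene-end peaks and did pass (camera adjusted p = 6.53e-06). Cd44 and Hmga2 had lower peaks (−0.95 ± 0.23 and −1.01 ± 0.26). AP-1 family genes had 13 of 243 peaks higher and 31 lower (16 and 35 adjusted over the list alone), with Fosl2 and Jdp2 (0.86 ± 0.18) among the higher and Fos and Junb (−0.88 ± 0.17) among the lower. The mean of this list lay below that of other peaks by −0.16 (camera adjusted p = 0.00998; adjusted p = 0.156 with an estimated correlation), and its own mean of −0.13 became 0.08 under gene-end scaling. PRC2 and PRC1 subunit genes had 11 of 253 peaks higher and 30 lower (13 and 30 adjusted over the list alone). They lay −0.17 from other peaks (camera adjusted p = 0.0066; adjusted p = 0.0655 with an estimated correlation), their own mean of −0.15 becoming 0.06 under gene-end scaling. That list also holds the demethylase gene Kdm6b, which is not a subunit gene. From the list the rule takes peaks of both directions, among them peaks of the cofactor genes Jarid2 and Aebp2. The Jarid2 peak fell from 6.06 ± 0.433 to 1.99 ± 0.284 CPM (chromosome 13, 44907461 to 44907962; −1.62 ± 0.21). The Aebp2 peak rose by 1.47 ± 0.18, and a difference between the genes was not tested. Ezh2, the catalytic subunit, rose at a gene-body peak (chromosome 6, 47532454 to 47532955) from 3.79 ± 0.608 to 8.94 ± 0.579 CPM (1.21 ± 0.18; edgeR adjusted p = 1.65e-06). It rose at 2 others (0.73 ± 0.18 and 0.79 ± 0.18) and fell at a gene-end peak (−0.50 ± 0.17). Hox cluster genes had 5 of 310 peaks higher and 23 lower (2 and 10 adjusted over the list alone), with Hoxc13 rising by 1.47 ± 0.23 and Hoxb3 at −0.59 ± 0.16. The Hox mean lay −0.21 from other peaks (camera adjusted p = 0.00101; adjusted p = 0.0854 with an estimated correlation), and its own mean of −0.18 became 0.03 under gene-end scaling. Ribosomal protein genes, the reference list, had 11 of 233 peaks higher and 17 lower (11 and 14 adjusted over the list alone). They lay −0.17 from other peaks (camera adjusted p = 0.0147; adjusted p = 0.0699 with an estimated correlation), with an own mean of −0.14 that became 0.07 under gene-end scaling.

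None of the other 14 lists passed the camera test in early cells. Fibroblast identity genes had 74 of 943 peaks higher and 30 lower (64 and 28 adjusted over the list alone), with Prrx1, a mesenchymal homeobox gene, at 1.59 ± 0.20 and Postn, a matrix protein gene, at −1.39 ± 0.32. Myofibroblast and contractile genes had 23 of 377 higher and 18 lower (22 and 18 adjusted over the list alone), with Smtn at 1.5 ± 0.21. YAP-TEAD target genes had 49 of 546 higher and 29 lower (49 and 28 adjusted over the list alone), with Nt5e at 1.22 ± 0.19 and Crim1 at −1.17 ± 0.20. Senescence and p53 genes had 22 of 238 higher and 25 lower (23 and 27 adjusted over the list alone), with Cdkn2b at 1.5 ± 0.24 and Btg2 at −1.06 ± 0.17. Polycomb-bound developmental regulators had 84 of 1087 higher and 59 lower (77 and 53 adjusted over the list alone), with Tbx4 at 1.89 ± 0.21, Pax2 at 1.66 ± 0.18 and Pax3 at −1.63 ± 0.24. Chondrogenic and osteogenic genes had 35 of 302 higher and 12 lower (37 and 13 adjusted over the list alone), with Sox9 at 1.32 ± 0.21. Adipogenic genes had 22 of 283 higher and 15 lower (22 and 15 adjusted over the list alone), with Pparg at 1.03 ± 0.19 and Ebf2 at −1.21 ± 0.26. Among markers of other cell types, endothelial genes had 21 of 228 higher and 6 lower (20 and 6 adjusted over the list alone), and epithelial 26 of 191 and 10 (27 and 12). Macrophage genes had 11 of 105 and 3 (10 and 3), neuronal 32 of 255 and 15 (34 and 19) and skeletal and cardiac muscle 8 of 162 and 6 (7 and 5). Interferon response genes had 11 of 119 higher and 1 lower (9 and 1), and pluripotency genes 14 of 182 and 3 (13 and 3). The 38 gene-end peaks of interferon genes lay 0.16 above other gene-end peaks (camera adjusted p = 0.0273). Examples are Emcn, an endothelial surface protein gene (2.29 ± 0.34), Grhl2, an epithelial transcription factor gene (1.59 ± 0.23), Acta1 (1.63 ± 0.19) and Rsad2 (1.15 ± 0.17). For neuronal and pluripotency genes the mean was positive and the median and test negative, and for interferon genes the mean and median were negative and the test positive.

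The early split of called peaks, 67.2% higher, depended on the scaling. With TMM factors taken from gene-end peaks it was 93.3% higher (39571 higher and 2837 lower). That scaling raised the median log2 fold change of all peaks from −0.03 to 0.18 in early Fra2, from −0.01 to 0.23 in late Fra2 and from 0.00 to 0.14 in inhibitor cells. List means are therefore given relative to other peaks. Under that scaling the calls near PRC2 and PRC1 subunit genes were 25 higher and 9 lower, those near AP-1 family genes 37 and 12, near ribosomal protein genes 24 and 3, and near AP-1 target and wound genes 151 and 4. Near Hox genes all 19 were higher. Polycomb-bound regulators had 139 and 11, fibroblast identity genes 145 and 8, YAP-TEAD targets 89 and 7, myofibroblast genes 57 and 6, senescence and p53 genes 35 and 11, chondrogenic genes 63 and 2 and adipogenic genes 51 and 3. Neuronal genes had 49 and 4, epithelial 46 and 2, endothelial 40 and 2, pluripotency 29 and 1, macrophage 26 and 1, and muscle genes 18 and 2. All 46 higher and 40 of 45 lower early peaks that were named by the rule kept their call under it, and none changed direction. The early count was 19720 without early Fra2 replicate 1, and without early control 3 the peaks of Col11a2 (−0.59) and Sox17 (−0.51) were among those no longer called. The early call of the AP-1 family list was lost under cyclic loess scaling, where the list lay −0.15 from other peaks against −0.16.

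**Figure D2:**
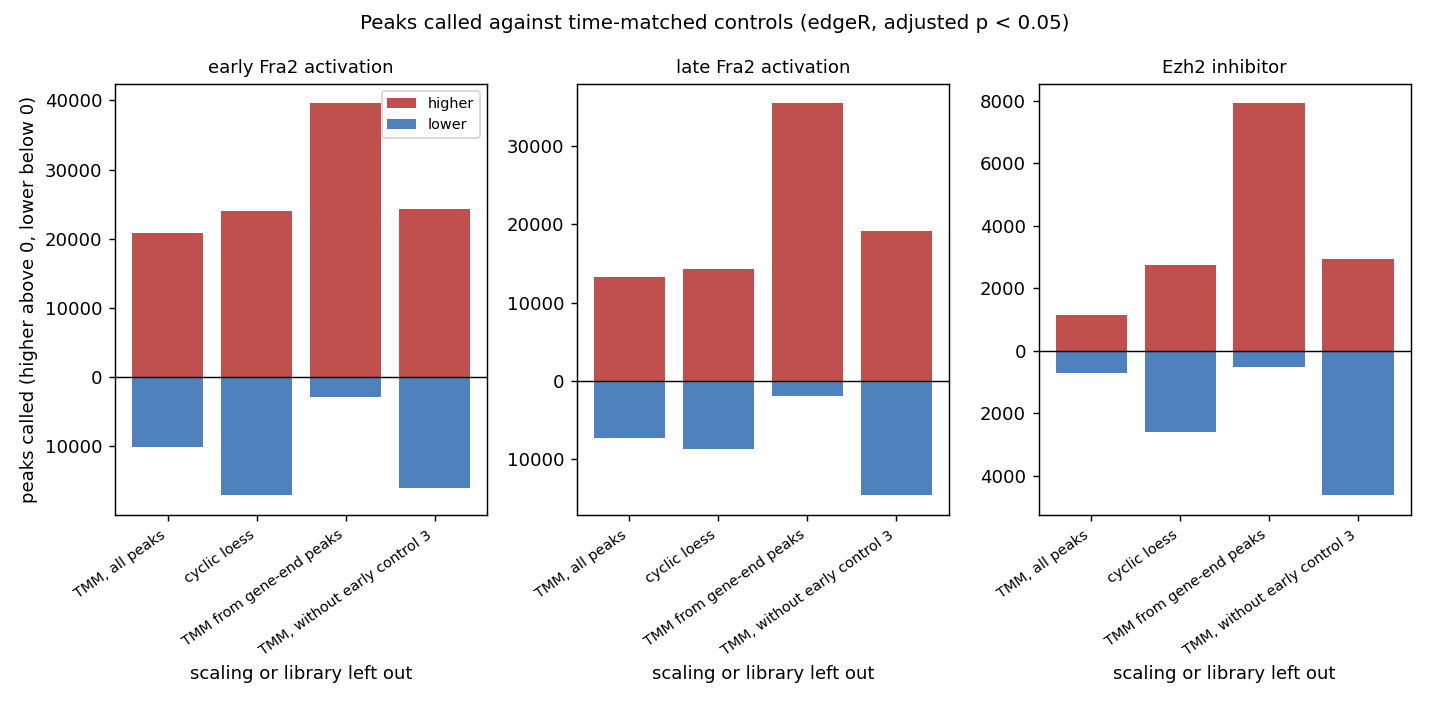
Number of peaks called higher and lower (y axis, lower peaks below 0, own scale in each panel) in each comparison under the main scaling, gene-end TMM and cyclic loess, and without early control 3 (x axis). The main counts were 20791 and 10144 for early Fra2, 13297 and 7306 for late Fra2, and 1139 and 704 for the Ezh2 inhibitor, and gene-end TMM raised the share of higher peaks to 93.3%, 95.1% and 93.8%.

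Late Fra2 activation, which asks about longer exposure against late controls, gave 13297 peaks called higher and 7306 called lower. Over 5 bins of rising mean accessibility the median log2 fold change went from 0.15 to −0.17. Under cyclic loess scaling it was −0.02 in the lowest and highest bin, with 14316 peaks called higher and 8725 lower. In the main scaling the median control level was 2.53 CPM at higher and 7.52 CPM at lower peaks. Ptgs2, an inducible prostaglandin synthase gene, rose at a peak 1.2 kb away (chromosome 1, 150109143 to 150109644) from 2.06 ± 0.717 to 5.3 ± 0.682 CPM (n = 3; log2 fold change 1.34 ± 0.22, SE; edgeR adjusted p = 4.42e-05). Twist1, a mesenchymal transcription factor gene, rose by 1.38 ± 0.20 at a peak 12.1 kb away. Pmaip1 and Mdm2, both p53 targets, rose by 1.36 ± 0.18 and 1.15 ± 0.27. Jarid2 lost at the peak that fell early (−1.30 ± 0.22), and Ezh2 gained at the same gene-body peak, from 4.03 ± 0.289 to 7.86 ± 1.28 CPM (0.96 ± 0.17; edgeR adjusted p = 0.000145).

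Among the largest late gains were Bcor, a transcriptional corepressor gene (2.5 ± 0.45), Grm8 (2.45 ± 0.43), Antxr2 (2.32 ± 0.43), Hadha, of mitochondrial fatty acid oxidation (2.30 ± 0.44), Krtap1-5 (2.29 ± 0.32), Lrmda (2.28 ± 0.41) and Oacyl (2.26 ± 0.34). The largest losses were at Klhl22 (−2.44 ± 0.55), Pmch, a neuropeptide precursor gene (−2.36 ± 0.48), Hhat, the acyltransferase of Hedgehog proteins (−2.18 ± 0.26), Gse1 (−2.12 ± 0.41), Ttll7 (−2.04 ± 0.50), Frmd8 (−1.96 ± 0.49), Colec10 (−1.96 ± 0.51) and Hmgcll1 (−1.91 ± 0.48). Of these losses Hhat was the best determined, at 0.892 ± 0.267 CPM against 4.0 ± 0.395 in controls (edgeR adjusted p = 8.59e-08).

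AP-1 target and wound genes had 67 of 669 peaks higher and 8 lower in late cells (79 and 10 adjusted over the list alone). Their mean lay 0.17 above other peaks (camera adjusted p = 0.000597; adjusted p = 0.0244 with an estimated correlation), with an own mean of 0.21 and, under gene-end scaling, of 0.45. Ccl2, a chemokine gene, and Hmga2 fell within that list (−1.09 ± 0.21 and −1.16 ± 0.25). AP-1 family genes had 11 of 243 peaks higher and 16 lower (11 and 20 adjusted over the list alone), with Atf3 at 0.97 ± 0.26 and Fos at −1.0 ± 0.22. The list lay −0.16 from other peaks (camera adjusted p = 0.00594; adjusted p = 0.117 with an estimated correlation), its own mean of −0.11 becoming 0.12 under gene-end scaling. Hox cluster genes had 1 of 310 higher and 19 lower (1 and 14 adjusted over the list alone): Hoxc13 rose by 0.74 ± 0.20, and Hoxb13 (−1.20 ± 0.25) and Hoxa3 (−0.99 ± 0.17) fell. The Hox mean lay −0.24 from other peaks (camera adjusted p = 1.43e-05; adjusted p = 0.0591 with an estimated correlation), and its own mean of −0.20 became 0.04 under gene-end scaling. PRC2 and PRC1 subunit genes had 8 of 253 higher and 23 lower (10 and 27 adjusted over the list alone). Of the 23 lower peaks 7 were at Kdm6b, the demethylase gene in that list, which is not a subunit gene. The list lay −0.17 from other peaks (camera adjusted p = 0.00436; adjusted p = 0.0591 with an estimated correlation), with an own mean of −0.13 that became 0.11 under gene-end scaling. Ribosomal protein genes had 4 of 233 higher and 8 lower (3 and 6 adjusted over the list alone). They lay −0.15 from other peaks (camera adjusted p = 0.0147; adjusted p = 0.0699 with an estimated correlation), with an own mean of −0.11 that became 0.13 under gene-end scaling. Under cyclic loess scaling the late calls of the AP-1 family and ribosomal lists were lost, at −0.10 and −0.12. Gene-end peaks made up 99 of 310 Hox, 89 of 233 ribosomal, 46 of 243 AP-1 family and 47 of 253 PRC2 and PRC1 subunit peaks. Among all tested peaks the share was 26742 of 206349. Gene-end peaks lay below other peaks in each comparison, so the place of their peaks can enter the gaps of these lists. With gene-end peaks alone, of which the lists hold fewer, every list call below other peaks was lost. The AP-1 family, Hox, PRC2 and PRC1 subunit and ribosomal lists then lay −0.12, −0.06, −0.07 and −0.02 from other gene-end peaks in early and −0.01, −0.10, −0.12 and −0.01 in late cells, where the test of the AP-1 family and ribosomal lists was positive.

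The other 14 lists did not pass the camera test in late cells. Myofibroblast and contractile genes had 32 of 377 peaks higher and 13 lower (32 and 13 adjusted over the list alone), and Tpm1, a tropomyosin gene, rose by 0.97 ± 0.17 at a gene-end peak while a peak 62.6 kb away fell by 0.72 on the log2 scale. Fibroblast identity genes had 38 of 943 higher and 27 lower (30 and 17 adjusted over the list alone), with Zeb2 at −0.81 ± 0.17. YAP-TEAD target genes had 32 of 546 higher and 22 lower (32 and 22 adjusted over the list alone), with Amotl2 at 1.08 ± 0.19 and Ccn1 at −0.74 ± 0.16. Polycomb-bound developmental regulators had 41 of 1087 higher and 40 lower (33 and 27 adjusted over the list alone), with Dlx2 at 1.39 ± 0.20, Lhx2 at 1.35 ± 0.23 and Otx1 at −0.82 ± 0.15. Senescence and p53 genes had 10 of 238 higher and 4 lower (9 and 4 adjusted over the list alone). Chondrogenic and osteogenic genes had 12 of 302 and 13 (12 and 13), with Runx2 at 0.95 ± 0.17, and adipogenic genes 9 of 283 and 13 (9 and 12). Endothelial genes had 7 of 228 higher and 8 lower (7 and 7), and epithelial 16 of 191 and 6 (18 and 7). Macrophage genes had 1 of 105 and 3 (1 and 1), neuronal 16 of 255 and 4 (12 and 4) and skeletal and cardiac muscle 5 of 162 and 7 (4 and 4). Interferon response genes had 9 of 119 higher and 4 lower (9 and 4), with Oas1a, an antiviral enzyme gene, at −1.13 ± 0.21, and pluripotency genes 9 of 182 and 8 (8 and 7). The mean, median and test differed in sign for epithelial and macrophage genes, and for interferon genes the mean and median were positive and the test negative.

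The late count moved with single libraries. It was 33784 without early control 3, which enters through the shared estimate of spread, 10063, 9643 and 13599 without late Fra2 replicates 1, 2 and 3, and 10744 and 8832 without late controls 2 and 3. With gene-end TMM 95.1% of late calls were higher (35481 higher and 1842 lower) against 64.5% in the main result, and 83.3% of those with an absolute log2 fold change of at least 1 were higher in the main scaling. With gene-end TMM the late calls near AP-1 target and wound genes became 195 higher and 2 lower, near Hox genes 6 and 2, near PRC2 and PRC1 subunit genes 27 and 5, near AP-1 family genes 31 and 3 and near ribosomal protein genes 19 and 2. Fibroblast identity genes had 128 and 3, Polycomb-bound regulators 123 and 8, YAP-TEAD targets 81 and 3, myofibroblast genes 73 and 1, chondrogenic genes 46 and 4 and adipogenic genes 41 and 3. Endothelial genes had 36 and 3, epithelial 34 and 1, pluripotency 25 and 2, muscle 22 and 2, macrophage 19 and 1 and interferon genes 16 and 2, and the 52 near neuronal and 31 near senescence and p53 genes were all higher. Of 90 named late peaks 72 were still called without late control 3, and 44 of 44 higher and 37 of 46 lower ones were called in the same direction with gene-end TMM.

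**Figure D3:**
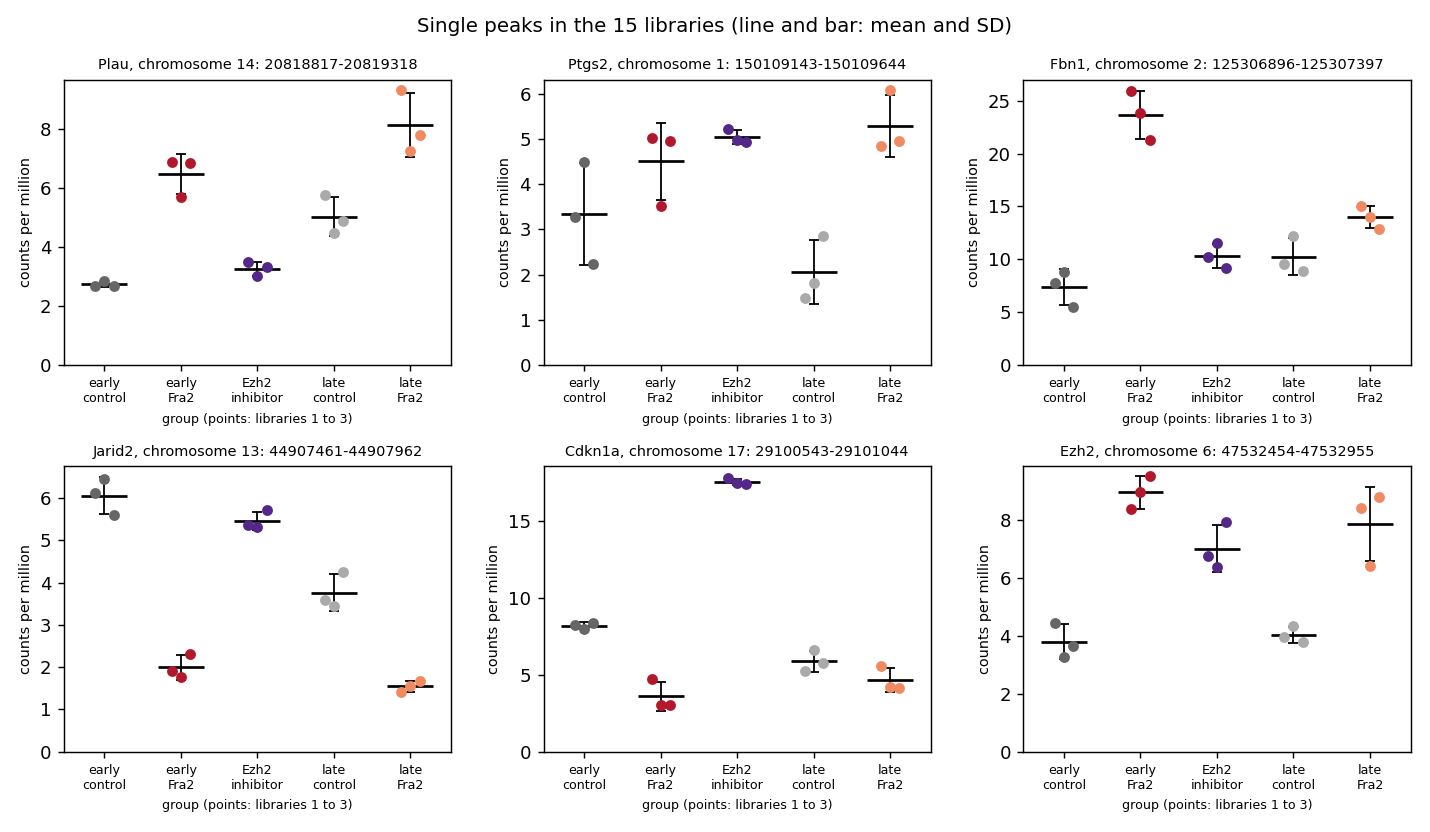
CPM in each library (y axis) for peaks at Plau, Ptgs2, Fbn1, Jarid2, Cdkn1a and Ezh2, with 1 point per library and lines for mean and SD, grouped along the x axis by the 5 groups of 3 libraries. The Cdkn1a peak stood at 8.2 CPM in early controls, 3.59 in early Fra2 and 17.6 in inhibitor libraries, and the Fbn1 peak rose from 7.34 to 23.7 CPM in early cells.

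Whether the Fra2 effect itself differed between times was tested directly. At 193 peaks it did, with 169 effects smaller and 24 larger in late cells. At the smaller ones the median log2 fold change went from 1.26 in early to −0.01 in late cells, a gap that their selection by this difference enlarges. Over all peaks called higher in early Fra2, selected on the early value, the median was 0.89 in early and 0.49 in late cells. Of all early calls 90.6% kept their sign in late cells. Fbn1 went from 1.65 to 0.45 at the peak described above (difference −1.20 ± 0.23; edgeR adjusted p = 0.0149). Peaks chosen after their values were seen include the nearest to Olfr654, from 1.83 to −0.14 (difference −1.97 ± 0.26; edgeR adjusted p = 5.95e-05). Others are Nsd2, a histone methyltransferase gene, from 1.20 to −0.52, and Id1, a regulator of differentiation, from −1.11 to 0.25 (difference 1.36 ± 0.24; edgeR adjusted p = 0.00422). Across all peaks the early and late effects, which have separate controls, correlated with Pearson's r = 0.585 and Spearman's rho = 0.563, across peaks that are not independent replicates. Both comparisons called 7351 peaks higher, where independent lists would share 1339.8, and 1603 lower against 359.2, and 20 peaks were called in opposite directions against 1389.8. DESeq2 called 366 peaks for the difference between times. The count of 193 was 109, 119 and 116 without inhibitor replicates 1, 2 and 3, 39 and 38 without early Fra2 replicates 1 and 2. It was 579, 71 and 531 without early controls 1, 2 and 3, 101, 31 and 29 without late Fra2 replicates 1, 2 and 3, and 117, 22 and 68 without late controls 1, 2 and 3.

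The Ezh2 inhibitor, a blocker of the methyltransferase that deposits the repressive mark on histone H3 lysine 27, was compared with early controls, which the series design puts on the same day, while the sample labels give day 3 for early controls 1 and 2 and day 4 for the others. Accessibility rose at 1139 peaks and fell at 704. Cdkn1a, a cell-cycle inhibitor gene, rose at the gene-end peak that fell with early Fra2, from 8.2 ± 0.208 to 17.6 ± 0.254 CPM (n = 3; log2 fold change 1.10 ± 0.16, SE; edgeR adjusted p = 5.96e-05). Cd44, the hyaluronan receptor gene, rose by 0.95 ± 0.17 at a peak 2.6 kb away (edgeR adjusted p = 0.0026). Col1a1, the gene of a main chain of collagen, fell from 8.75 ± 0.32 to 4.81 ± 0.255 CPM at a peak 1.5 kb away (−0.87 ± 0.17; edgeR adjusted p = 0.005). Ezh2 itself, the inhibitor's target, rose from 3.79 ± 0.608 to 7.0 ± 0.82 CPM at the gene-body peak that also rose with Fra2 (0.86 ± 0.18; edgeR adjusted p = 0.011).

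The genes of largest gain were Speer1 (2.29 ± 0.60), Adgrv1 (1.96 ± 0.53), Tro (1.76 ± 0.39), Nfat5, the gene of an osmotic stress transcription factor (1.65 ± 0.35), Brinp1 (1.57 ± 0.25), Rtl4 (1.57 ± 0.40), Dpp10 (1.52 ± 0.39) and Tmtc2 (1.5 ± 0.40). All 8 were still called without early control 3. The largest losses were at Crocc (−2.09 ± 0.47), Smok2a (−2.06 ± 0.51), Zfp600 (−2.01 ± 0.47), Bub3, of the spindle checkpoint (−1.99 ± 0.49), Zfp992 (−1.95 ± 0.41), 2610301B20Rik (−1.90 ± 0.50), Gm32719 (−1.87 ± 0.43) and Gm39469 (−1.84 ± 0.34). In all 8 losses early control 3 had the highest level of the controls. Without it only Bub3 (−1.59), Gm32719 (−1.38) and Gm39469 (−1.26) of the 8 were called, with Crocc at −1.34, Smok2a at −1.40, Zfp600 at −0.73, Zfp992 at −0.86 and 2610301B20Rik at −0.93.

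Polycomb-bound developmental regulators are repressed by PRC2 in many cell types. With the inhibitor they had 5 of 1087 peaks higher and 9 lower (10 and 23 adjusted over the list alone). Under gene-end scaling the calls were 35 higher and 8 lower, where 93.8% of all inhibitor calls were higher. Gsx2 and Sim2 rose (1.0 ± 0.23 and 1.0 ± 0.24), and Gata4 and Sox17 fell (−1.14 ± 0.25 and −1.89 ± 0.40), the last only in a comparison with early control 3, without which it stood at −0.33. The mean of the list lay −0.10 from other peaks and did not pass (camera adjusted p = 0.119). Under cyclic loess it lay −0.10 from other peaks as well and passed (camera adjusted p = 0.0472). AP-1 target and wound genes had 17 of 669 higher and 1 lower (30 and 8 adjusted over the list alone), the lower one near Hbegf (−0.68 ± 0.18), and the list did not pass (camera adjusted p = 0.378). Senescence and p53 genes had 3 of 238 higher and 2 lower (4 and 3 adjusted over the list alone), with Btg2 higher (0.74 ± 0.16) and Zmat3 and Bax lower (−0.69 ± 0.18 and −1.16 ± 0.28), Bax not called without early control 3, at −0.91. Fibroblast identity genes had 6 of 943 higher and 6 lower (10 and 11 adjusted over the list alone), with Snai1 at 1.18 ± 0.23, Fbln2 at 0.78 ± 0.17 and Thy1, the gene of the protein used to sort the transduced cells, at −0.66 ± 0.17. PRC2 and PRC1 subunit genes had 1 of 253 higher and 2 lower (1 and 4 adjusted over the list alone), with Kdm6b, a demethylase gene of the same histone mark, at −0.64 ± 0.17. The list lay −0.09 from other peaks (camera adjusted p = 0.0358; adjusted p = 0.0854 with an estimated correlation), its own mean of −0.09 becoming 0.05 under gene-end scaling. AP-1 family genes and Hox genes lay −0.13 from other peaks (camera adjusted p = 0.000957 and 0.00127; adjusted p = 0.09 and 0.0854 with an estimated correlation), own means of −0.13 becoming 0.02 in both under gene-end scaling. All 3 calls were lost with gene-end peaks alone, where PRC2 and PRC1 subunit genes lay −0.10 from other gene-end peaks (47 of their peaks), AP-1 family genes −0.06 and Hox genes 0.005.

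In 7 lists with 1400 peaks edgeR called 0 with the inhibitor (0 adjusted over the list alone), and 182 of these peaks had an unadjusted p under 0.05. They were the AP-1 family, Hox, interferon, endothelial, macrophage, ribosomal, and skeletal and cardiac muscle lists, and DESeq2 called 1 peak, near an endothelial gene. YAP-TEAD target genes had 3 of 546 higher and 2 lower (3 and 2 adjusted over the list alone), with Tead4 at 1.20 ± 0.29 and Amotl2 at −0.84 ± 0.22. Myofibroblast and contractile genes had 4 of 377 and 2 (7 and 3). All of these 4 higher and 2 lower peaks were at Tpm1, where the named higher peak rose by 0.90 ± 0.17. Lower peaks alone were called near chondrogenic and osteogenic genes (4 of 302, 4 adjusted over the list alone; Sox5 −1.01 ± 0.23, and Sox9 −1.40 ± 0.34, which was −0.70 and not called without early control 3). The same held for adipogenic genes (2 of 283, 2; Adipoq −0.92 ± 0.22, Zfp423 −1.22 ± 0.31). It held for neuronal (2 of 255, 2; Rbfox3 −0.92 ± 0.22, and Elavl3 −1.74 ± 0.39, which was −1.13 and not called without early control 3), epithelial (1 of 191, 5; Cldn3 −0.89 ± 0.21) and pluripotency genes (1 of 182, 1; Fgf4 −1.47 ± 0.36). Gene-end scaling, under which 93.8% of all inhibitor calls were higher, turned these balances. Chondrogenic genes then had 10 higher and 3 lower, adipogenic 19 and 1, neuronal 9 and 2, epithelial 4 and 1 and pluripotency genes 3 and 1. With it fibroblast identity genes had 30 and 4, myofibroblast genes 22 and 1, and senescence and p53 genes 12 and 1. All 44 calls near AP-1 target and wound genes, 15 near YAP-TEAD targets and 8 near PRC2 and PRC1 subunit genes were then higher. So were 4 each near interferon, endothelial and ribosomal protein genes, 2 each near AP-1 family, macrophage and muscle genes and 1 near a Hox gene. For pluripotency genes the median was positive and the mean and test negative, and for muscle genes the mean was negative and the median and test positive.

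The inhibitor count rested on the libraries more than the Fra2 counts did. It was 281, 366 and 220 without inhibitor replicates 1, 2 and 3, and 3303, 348 and 7565 without early controls 1, 2 and 3, the last with 38.8% higher against 61.8% in the main result, and a fit of these 6 libraries alone called 11. Under gene-end TMM 93.8% of 8453 called peaks were higher and under cyclic loess 51.5% of 5353, and 51.4% of 521 with an absolute log2 fold change of at least 1 in the main scaling. Without inhibitor replicate 3 only 9 of 47 named peaks were called. No vehicle-treated group was used here, the controls carried the activation construct and scrambled guides, and the inhibitor libraries have other sheet numbers, so treatment, transduction, sorting and batch cannot be told apart.

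**Figure D4:**
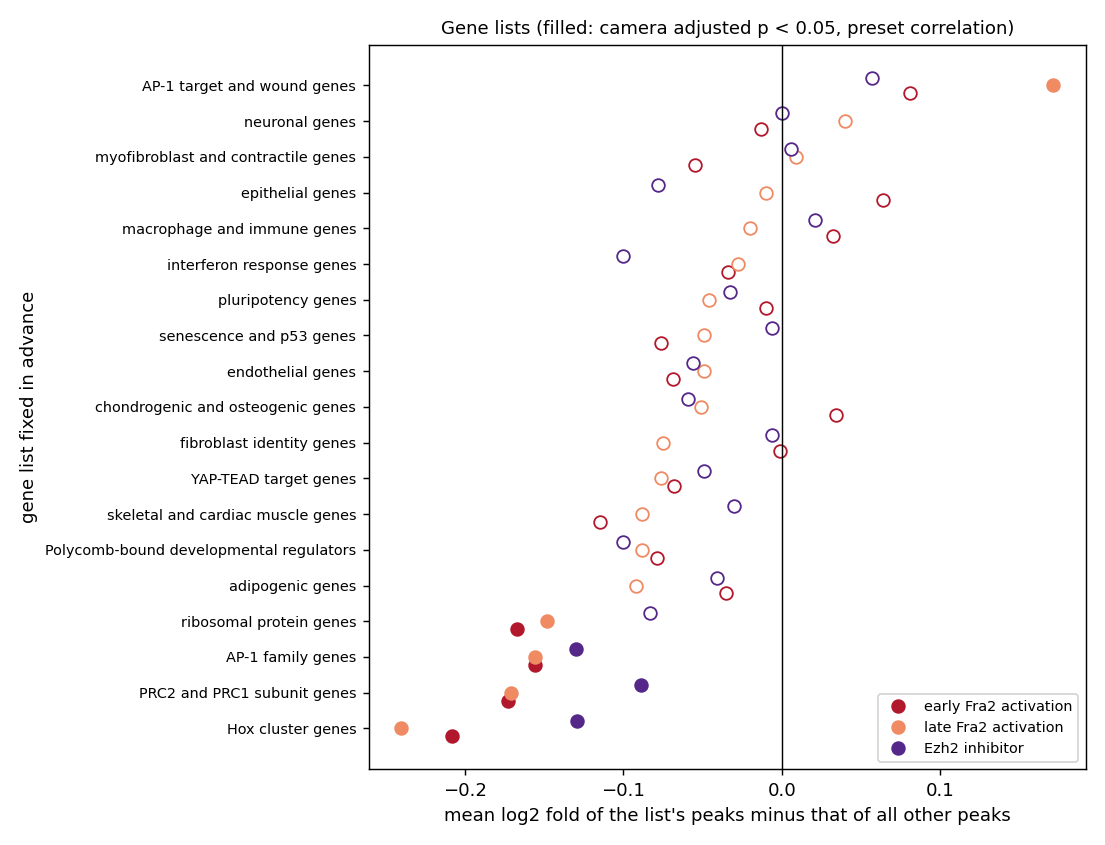
Mean log2 fold change of each gene list minus that of all other peaks (x axis) for the 19 lists (y axis) in the 3 treatment comparisons, with filled points for lists that passed the camera test at the preset correlation. AP-1 target and wound genes lay above other peaks in late Fra2 (0.17). AP-1 family, Hox and PRC2 and PRC1 subunit genes lay below in all 3 comparisons. So did the ribosomal reference list (−0.17, −0.15 and −0.08), which was called in early and late Fra2. The calls below other peaks were lost with an estimated correlation, and the own means of these lists turned positive under gene-end scaling.

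Early Fra2 and Ezh2 inhibitor were also compared directly, which removes the shared controls. They differed at 29349 peaks, 18613 higher in early Fra2 and 10736 lower. The count was 18885 and 16776 without inhibitor replicates 2 and 3 and 17623 without early Fra2 replicate 1, and under gene-end TMM 77.2% of the calls were higher in early Fra2 against 63.4%. The effects of both treatments against the early controls had r = 0.431 across peaks, where unchanged groups simulated against the same controls gave 0.549. Their covariance was 0.0756 against a simulated 0.0373, a difference of 0.0383. The simulation gave all groups the same spread per peak, while early control 3 stood further from its group (lowest correlation 0.783). The simulated covariance may therefore be too small and the difference too large. Both treatments called 773 peaks higher, where independent lists would share 114.8, 222 lower against 34.6, and 23 in opposite directions against 126.9. The simulated groups had at most 1 call per run by edgeR and so give no benchmark for these shared calls. With 3 controls these cannot be split, and part of the excess may come from the shared controls. Late Fra2 and Ezh2 inhibitor effects, whose controls are separate, had r = 0.295 and rho = 0.309, and shared 554 higher calls against 73.4 for independent lists, 132 lower against 24.9 and 12 opposite against 85.7.

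The place of the changes differed from that of the peaks. Under the main scaling 2.18% of gene-end peaks rose and 7.87% fell with early Fra2, against 12.69% and 3.86% outside genes and 10.06% and 4.99% in gene bodies. In late Fra2 1.25% of gene-end peaks rose and 8.99% fell, against 8.23% and 2.25% outside genes, and with the inhibitor 0.15% rose and 0.57% fell, against 0.67% and 0.33%. The odds of a rise at gene ends relative to elsewhere were 0.176 (95% interval 0.161 to 0.191) in early Fra2, 0.162 (0.145 to 0.181) in late Fra2 and 0.237 (0.168 to 0.326) with the inhibitor. The odds of a fall were 1.82 (1.73 to 1.92), 3.52 (3.34 to 3.7) and 1.85 (1.54 to 2.22; Fisher's exact test p = 2.17e-10), with peaks as units that are not independent replicates. Under cyclic loess the odds of a fall were 2.62, 1.69 and 2.82, so their order over the comparisons depends on the scaling, and the median log2 fold change of gene-end peaks was −0.21, −0.14 and −0.12. Median gene-end log2 fold changes of −0.22, −0.23 and −0.15 became −0.01, 0.01 and 0.00 when gene-end peaks set the scale, which centres them near 0 by construction and leaves the gap to other peaks as it was. Under that scaling 5.15% of gene-end peaks rose and 1.77% fell in early Fra2, 4.58% and 2.09% in late Fra2, and 1.21% and 0.51% with the inhibitor. What holds is therefore the difference between gene-end and other peaks, not a fall of the former. Gene-end peaks held 24.8 ± 1.58% of reads in early controls (SD, n = 3), 24.0 ± 1.2% in late controls, 21.4 ± 0.632% in early Fra2, 20.7 ± 0.255% in late Fra2 and 22.6 ± 0.13% in inhibitor libraries.

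**Figure D5:**
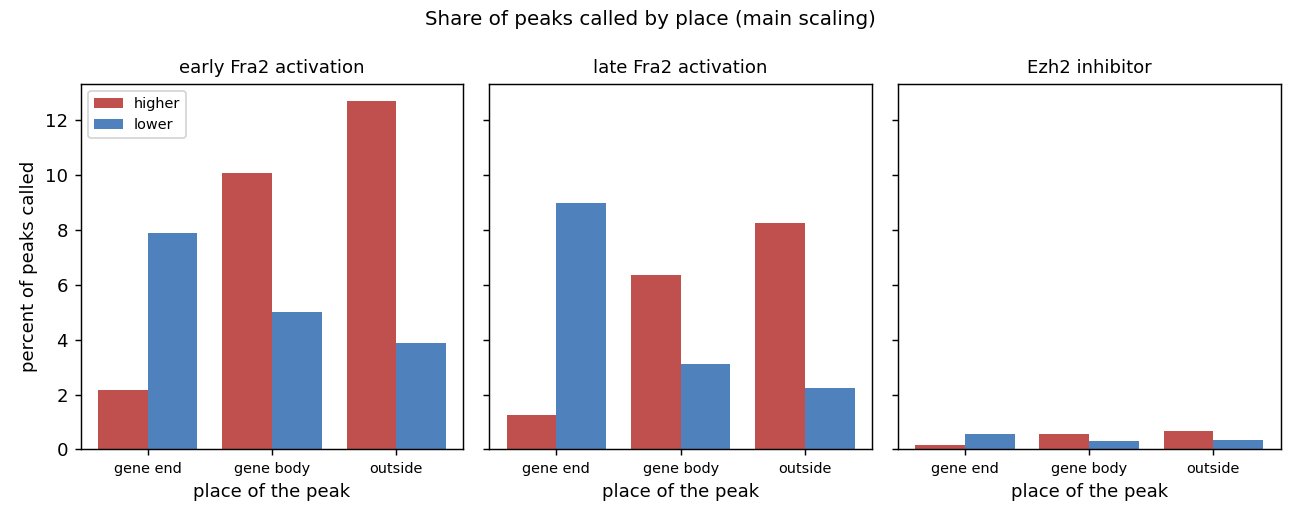
Percentage of tested peaks called higher and lower (y axis) at gene ends, in gene bodies and outside genes (x axis) in the 3 treatment comparisons. In early Fra2 12.69% of peaks outside genes and 2.18% of gene-end peaks rose, under the main scaling.

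The deposited peak lists gave 166467 ± 24766 merged regions in early Fra2 against 141687 ± 38058 in early controls (SD, n = 3; two-sided exact permutation p = 0.5). Late Fra2 libraries had 204690 ± 15846 regions against 153001 ± 21414 (exact permutation p = 0.1), and inhibitor libraries 209012 ± 9841 (exact permutation p = 0.1 against early controls). The smallest p that 3 against 3 libraries allow is 0.1. Early control 3, the shallowest library, had 101755 regions, and depth differed between the groups, so these counts do not separate depth from accessibility.

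Late and early scrambled controls, compared as a background for the comparisons at each time, differed at 6766 peaks, of which 4218 were more accessible late. A peak of Pde4d, a cyclic AMP phosphodiesterase gene (chromosome 13, 108834517 to 108835018), was higher in late than in early controls, from 1.91 ± 0.494 to 7.05 ± 1.12 CPM (1.97 ± 0.23; edgeR adjusted p = 1.58e-07), and was chosen after its values were seen. The count was 3339 without early control 2, 2299 and 3910 without late controls 2 and 3, and under gene-end TMM 79.3% of calls were higher against 62.3%. Among calls with an absolute log2 fold change of at least 1 the balance turned, with 648 peaks more and 1190 less accessible late (35.3% higher).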

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

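The test of the time difference was planned, and the alternative labellings of the libraries were written down before their result was seen. The Fra2 effect differed between early and late cells at 193 peaks, and it was this difference between groups that marked the result for a closer look. Of 41 labellings within the times, 2 gave at least as many calls, the real one (191 in the fit used for this) and one with 5730, the cause of which was not tested. The other 40 were a random draw of the possible labellings. Mixing treated with control libraries puts the Fra2 effect itself into the spread within groups, which lowers calls. These labellings therefore cannot say whether the difference arose by chance. The effect of Fbn1 fell from 1.65 to 0.45 and that of Pfkfb3, a glycolysis regulator gene, from 2.39 to 0.74, while peaks at Fn1, the fibronectin gene, and Gap43 went from −0.74 to 0.81 and from −1.43 to 1.77. The last 3 were chosen after their values were seen. At the peaks of Pde4d, Spice1 and Rai14 among the 193, late controls stood above early controls (log2 fold change 1.97, 1.95 and 2.35). The Fra2 effect there changed by −1.57, −1.76 and −2.89, so a rise of the controls enters these differences. These peaks were taken from the largest control differences, and the rest of the 193 were not tallied this way. Which cells, days in culture or batches carry the difference was not tested.

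Of the tests in this paragraph, both on the gene-end pattern were written before their result was seen. Gene-end peaks lay below other peaks in both Fra2 comparisons, a relative difference, since their own direction depends on the scaling. Scaling that depends on accessibility is argued against by the median difference between gene-end and other peaks within bins of similar accessibility, −0.194 in the weaker comparison, and early control 3 by −0.202 in the early comparison without it. What stays open is a difference in library preparation that acts on gene ends at any accessibility, since the controls held more reads there, and batch, neither of which was tested.

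Of the tests in this paragraph, that on shared controls was written after the result was seen and the other 2 before. Ezh2 inhibitor effects lay in the direction of Fra2 effects, with r = 0.295 against late Fra2, which has its own controls. The lowest r with any library left out was 0.207, which argues against the shared early controls as the whole cause. It was 0.301 under cyclic loess and 0.364 without early control 3, which argues against scaling by accessibility and against that library. A property common to all controls and absent from treated libraries could give the same pattern and was not tested.

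The splits were written before their result was seen. With 10 splits of 6 libraries the splits are too few for a small share. In each comparison only 1 split, the real one, gave as many calls: 30813 in early Fra2 (highest other 72), 20380 in late Fra2 (0), 1794 with the inhibitor (48), 6741 between controls (8) and 29170 between early Fra2 and inhibitor (0). Every other split mixes libraries of both groups, which puts the difference between the groups into the spread and lowers calls. These splits therefore cannot say whether the differences arose by chance.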

How the results depend on the processing

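Of the main counts and correlations 316 alternative values were counted as holding and 68 as moved. Holding did not mean unchanged. Early Fra2 peaks were counted as holding at 42408 (39571 higher) with gene-end TMM and 41021 with cyclic loess. The main result was 30935 (20791 higher). The time difference was counted as holding at 253 peaks with a replicate block, against 193. Of the other values 6061 stayed, 348 became weaker, 21 stronger and 2 reversed. For values that moved the cause was not tested, except where fewer libraries, reads or peaks explain it. Counts moved as follows. Early Fra2 peaks were 17033 after thinning, 15004 with own groups only and 10386 at a log2 fold change of at least 1. Late Fra2 peaks were 37323 with gene-end TMM, 33356 with quality weights, 6150 thinned, 33257 with own groups and 5471 at the fold threshold. Inhibitor peaks were 2942 with total counts, 8453 with gene-end TMM, 5353 with cyclic loess, 5326 with quality weights, 429 thinned, 11 with own groups, 15611 with own groups and no early control 3, and 521 at the fold threshold. Peaks that differ between times were 413 with gene-end TMM, 586 with loess, 366 with DESeq2, 424 with quality weights, 45 thinned and 67 with own groups. Control time peaks were 2827 thinned, 1133 with own groups and 1838 at the fold threshold, and early Fra2 against inhibitor 11321 thinned and 8694 at the threshold. Of 12 list calls 1 held with estimated correlation. With gene-end peaks only 3 lists were called, of which 1 was among the 12. Of list values called in either setting, the interferon response genes reversed in early Fra2 (0.164) and the Hox genes with the inhibitor (0.005) with gene-end peaks only, where several lists called in neither also changed sign, and under loess 1 Fosl2 peak was called with the inhibitor.

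Leaving out each library gave 19720 to 40321 peaks in early Fra2, 8832 to 33784 in late Fra2, 220 to 7565 with the inhibitor, 22 to 579 for the time difference, 2299 to 8685 for control time and 16776 to 39611 for early Fra2 against inhibitor. Correlations of effects ranged from 0.512 to 0.612 (early and late Fra2), 0.207 to 0.364 (late Fra2 and inhibitor) and 0.392 to 0.547 (early Fra2 and inhibitor). Ratios of peak regions ranged from 1.03 to 1.35, 1.24 to 1.41 and 1.29 to 1.69, and called Fosl2 peaks from 6 to 11, 6 to 13 and 0 to 4. Of the named peaks 83 to 91 of 91, 72 to 90 of 90 and 9 to 47 of 47 were still called. Libraries of the same number in different groups correlated at −0.192 to 0.262 and 6 of 15 had their best partner at the same number, so they are not taken as paired, and a replicate block changed no count of calls by over 1.5 times. Motif searches and a GC offset were not run, since no genome was used here.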

Other observations

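The interferon tests of this part and the list tests over time were written after their results were seen, and the peaks here were chosen after their values were seen. Camera p-values of the list tests over time were adjusted over the 19 lists of that comparison alone. Interferon response genes were less accessible in late than in early controls, both with scrambled guides. Isg15, a ubiquitin-like antiviral gene, fell from 10.6 ± 2.13 to 4.04 ± 1.38 CPM (chromosome 4, 156200599 to 156201100; SD, n = 3; log2 fold change −1.40 ± 0.19, SE; edgeR adjusted p = 3.74e-06), Stat2 at −1.38 ± 0.26 (edgeR adjusted p = 0.000874) and Rsad2 at −1.13 ± 0.24. Of 119 peaks of the list 2 rose and 14 fell (3 and 22 adjusted over the list alone), with Irf1 and Oasl2 the higher (0.71 ± 0.18 and 0.91 ± 0.28). The list mean lay −0.28 from other peaks (camera adjusted p = 1e-05; adjusted p = 0.00206 with an estimated correlation), with the same direction under all scalings. AP-1 target and wound genes lay 0.14 above other peaks, with 29 of 669 higher and 9 lower (41 and 13 adjusted over the list alone; camera adjusted p = 0.0142; adjusted p = 0.04 with an estimated correlation). Senescence and p53 genes lay −0.11 from other peaks, with 1 of 238 higher and 11 lower (4 and 14 adjusted over the list alone; camera adjusted p = 0.0142; adjusted p = 0.04 with an estimated correlation). AP-1 family genes lay −0.10 from other peaks, with 2 of 243 higher and 14 lower (3 and 19 adjusted over the list alone; camera adjusted p = 0.0193; adjusted p = 0.208 with an estimated correlation). Without early control 3 the interferon mean stayed at −0.272, between late and early Fra2 libraries it was −0.27, and under cyclic loess −0.277. These values argue against that library, against a change confined to the controls and against scaling by accessibility, while time in culture, cell density, passage and batch stay open.

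Some genes changed at many of their peaks, and these tallies were chosen after the values were seen. Csf1, the gene of a macrophage growth factor, gained at 16 of 53 peaks in early Fra2, 17 in late Fra2 and 13 with the inhibitor. Tnc, the tenascin gene, gained at 22, 9 and 8 of 107 peaks. Enah, an actin regulator gene, gained at 19 of 54 peaks in early and 15 in late Fra2. Gse1 lost at 25 of 145 peaks in early and 35 in late Fra2. Egr1, an immediate early gene, lost at 11, 5 and 2 of 15 peaks, and Per1, a clock gene, at 8 and 7 of 20 in early and late Fra2. Cdkn1a lost at 12 of 19 peaks in early Fra2 and gained at 2 with the inhibitor. In late Fra2 edgeR called 0 of the 19, DESeq2 called 2, and 7 had an unadjusted edgeR p under 0.05. Thbs1, the thrombospondin gene, gained at 1, 14 and 3 of 39 peaks. Late controls were lower than early controls at 7 peaks of Thbs1, 4 of Cdkn1a and 6 each of Egr1, Fos and Btg2. They were higher at 7 of Csf1 and 4 of Tnc, where 1 was lower. In Gse1 3 peaks rose in early Fra2.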
